A study of Mus musculus with 8 samples.

How the data were processed

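The deposited signal intensities were not normalized, per the file headers, and were read from the Illumina arrays by the authors, with a detection p-value for each probe on each array that the authors deposited beside them. The detection p-values move in 798 equal steps, which is what ranks among negative control probes give. The authors' processed intensities, in linear units, were made with lumi 2.10.0 in R 2.15.0 per the submitters' processing notes, and the normalization method is not given in the sources used here. The authors' processed values keep the rank order of the deposited signal on every array (rank correlation 1), equal it on WT replicate 2, and have medians between 194.7 and 195.7.

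The analysis started from the deposited signal intensities, whose columns were given to samples by the letters in the sample descriptions. With limma 3.58.1 in R 4.3.3, background was estimated from the detection p-values and removed by the normexp model with an offset of 16, and the arrays were quantile normalized and put on the log2 scale. Probes with a detection p-value under 0.05 on at least 4 of the 8 arrays were tested, 14190 in all, from 9782 named genes. Of the 25697 probes, 23978 carry 1 gene symbol in the platform table, 0 carry several and 1719 are not listed there. Genes were matched to the GRCm38.p6 annotation by Entrez ID (23962 probes), which was used for names, chromosomes and order of genes. The array files name no genome build.

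Differences are Bgn_KO minus WT from a linear model with moderated variances in limma, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Gene lists were tested with camera from limma on 1 probe per gene, that with the highest mean signal, with a preset correlation of 0.01 and again with a correlation estimated for each list. Of 41 lists, 37 had at least 5 measured members and were tested, and of their 1011 symbols 14 were renamed and 1 was not matched. Permutation p-values between the groups compare all splits of the arrays and are exact, and those for the placement of genes rest on 10000 random placements. The samples, the model, the lists, the thresholds and most alternatives were fixed before the data were examined.

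Genes are named by a rule: Bgn, the 12 probes with the largest rise and the 12 with the largest fall among those past 0.05 without overlap of the groups, 6 genes of feeding control, and up to 4 members of each list, those past 0.05 over all probes first, then those past it over the list alone, then those with the smallest p, given as values only. A gene named outside that rule is marked as chosen after its values were seen. The analysis was tested on simulated data with 200 changed probes in each of 5 simulations. It found 30% of changes of 0.5 on the log2 scale, 78% of 1, 92% of 1.5 and 99.2% of 2, with 0 of the wrong sign. Of its calls 6.03% were false, and 0 probes and 1 list were called in simulations without any change. The simulations drew each probe independently, while the estimated correlation within the meningeal fibroblast list, for example, was 0.87. They therefore do not give the rate of false list calls in these data. Other splits of the real arrays into 4 and 4 gave up to 14 lists.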

Results

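Gene expression was measured in the hypothalamus of male mice aged 13 weeks, 4 carrying a disrupted Bgn gene (Bgn_KO) and 4 wild type (WT), all on a C57BL/6 background per the labels. Each of the 8 arrays carried 25697 probes and stands for 1 labelled animal of its group. Between 13820 and 14502 probes per array were above background (53.8% to 56.4%), and the median deposited signal per array ranged from 180 to 225. After normalization the arrays correlated with each other with r between 0.976 and 0.990 across probes, which are not independent replicates. The number of arrays limits the precision: the median standard error of a log2 difference between the groups was 0.13.

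The comparison of Bgn_KO with WT asks which transcripts of the hypothalamus differ when Bgn, which encodes the matrix proteoglycan biglycan, is disrupted. Bgn had 1 annotated probe on the array (ILMN_2964042), and the GRCm38.p6 annotation places the gene on chromosome X. Its normalized log2 signal was 8.94, 9.01, 8.99 and 8.79 on the Bgn_KO arrays in order of replicate (8.93 ± 0.10, SD, n = 4). On the WT arrays it was 8.86, 10.44, 10.14 and 9.53 (9.74 ± 0.70, SD, n = 4). The array labelled WT replicate 1 was thus within the range of the Bgn_KO arrays, against its label, while the other WT arrays averaged 10.03 ± 0.47 (SD, n = 3). The difference, Bgn_KO minus WT, was -0.81 on the log2 scale (SE 0.29) and did not pass the test (limma adjusted p = 0.390, two-sided exact permutation p = 0.114; 4 against 4 arrays can give no p below 0.0286). The overlap depends on the scaling: with each array scaled to its median the array labelled WT replicate 1 was at 8.93, just above the highest Bgn_KO array at 8.92, and the difference was -0.90 (exact permutation p = 0.0286, limma adjusted p = 0.270). In the deposited signal, which is not scaled between arrays, it was at 736, against 544 to 643 on the Bgn_KO arrays and 918 to 1443 on the other WT arrays. Without the array labelled WT replicate 1 the difference was -1.11 (limma adjusted p = 0.0886, exact permutation p = 0.0286). Directions between the groups given here rest on the labels as deposited, including that of the array labelled WT replicate 1. The probe was above background on all 8 arrays. Whether it lies inside the disrupted part of the gene was not known here, and a probe outside that part would check no label. Of the 32 measured genes from the list of X-linked neighbours of Bgn, 16 were higher and 16 lower, and 0 passed 0.05, neither over all probes nor adjusted over the list alone. Among them were Emd, which encodes the nuclear envelope protein emerin (log2 difference 0.36, limma adjusted p = 0.155), and Slc10a3 (-0.41, limma adjusted p = 0.249).

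**Figure D1:**
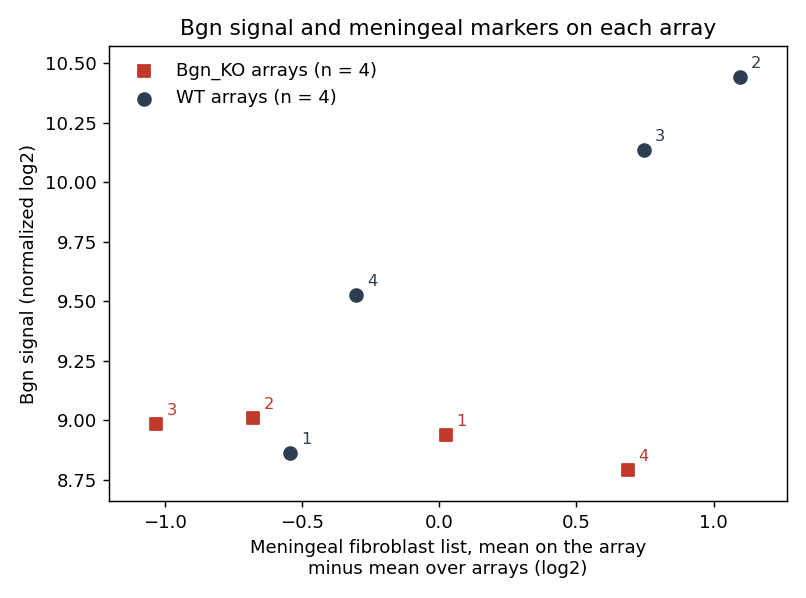
Normalized log2 signal of the Bgn probe on each array (vertical axis) against the mean of the meningeal fibroblast list on the array minus its mean over arrays, in log2 (horizontal axis). Each point is an array, numbered by replicate (squares Bgn_KO, n = 4, circles WT, n = 4). The Bgn_KO arrays lie between 8.79 and 9.01, and the array labelled WT replicate 1 lies among them at 8.86.

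Erdr1, a gene whose level is known to differ between mouse strains, had the largest rise: it was 9.76 ± 0.52 on the Bgn_KO arrays and not above background on any WT array (SD, n = 4 each), at least 21.9-fold higher in Bgn_KO (limma adjusted p = 1.02e-05). Serpina3n, a secreted protease inhibitor that astrocytes make in injury, was abundant in both groups and rose by 1.67 on the log2 scale (SE 0.12, 12.94 against 11.27, limma adjusted p = 2.34e-04). Padi2, which turns arginine in proteins into citrulline and is made by oligodendrocytes, rose by 2.28 (SE 0.16, limma adjusted p = 2.34e-04, at least 4.45-fold, with 2 WT arrays above background), and Rgs5, a pericyte regulator of G protein signals, by 1.60 (SE 0.21, limma adjusted p = 0.01). Where a probe was below background on arrays of a group, the fold is given as a bound: the mean of the brighter group against, per array of the other, the higher of the lowest signal above background and the probe's own signal. By that bound the interferon-inducible GTPase Gbp2b was at least 2.90-fold higher in Bgn_KO, 1700029J07Rik at least 2.69-fold, the somatostatin receptor Sstr1 at least 1.91-fold and the chemokine Ccl21a at least 1.89-fold. The Ccl21a probe and that of its near-identical paralog Ccl21b, which was chosen here after its values were seen and had a log2 difference of 0.77, may not tell the 2 genes apart. Dbpht2 rose by 2.06, Tpmt, the methyltransferase that inactivates thiopurine drugs, by 1.94 (at least 3.17-fold, with 1 WT array above background), Lcmt1, which methylates protein phosphatase 2A, by 1.63, and Ccnd1, cyclin D1, by 1.28. The other probes of Lcmt1 had log2 differences of 0.16 and -0.06, and those of Ccnd1 0.05 and -0.04. The call of Gbp2b was lost without Bgn_KO replicate 3 or any 1 WT array, the array labelled WT replicate 1 among them (limma adjusted p between 0.0531 and 0.0610). That of Dbpht2 was lost without Bgn_KO replicate 3 or without WT replicate 1, 2 or 4 (0.0531 to 0.0714). Tpmt was lost without Bgn_KO replicate 2, 3 or 4 or WT replicate 1, 3 or 4 (limma adjusted p 0.0786 to 0.122). Sstr1 was lost without Bgn_KO replicate 3 (0.0514) or WT replicate 1 (0.0531) or 3 (0.0564), and Ccnd1 without WT replicate 3 (0.0540). Gbp2b was also lost without background correction (limma adjusted p = 0.0510) and in the authors' processed values (0.0555), Sstr1 in the latter (0.0510) and Tpmt with no filter on dim probes (0.0511). Without Bgn_KO replicate 4 and WT replicate 4 together Rgs5 (limma adjusted p = 0.0670), Dbpht2 (0.0659) and Tpmt (0.194) were lost.

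Among genes that were lower, Cxadr, a cell adhesion protein that viruses use as a receptor, fell by 3.20 on the log2 scale (SE 0.21, 5.03 ± 0.42 against 8.23 ± 0.27, SD, n = 4 each, limma adjusted p = 2.21e-04). Its probe was above background on only 1 Bgn_KO array, which makes it at least 7.07-fold lower. Taf12, a subunit of the general transcription factor TFIID, fell by 3.00 (SE 0.23), and Fastkd3 and Mrps27, both of which act in mitochondrial gene expression, fell with log2 differences of -2.80 (SE 0.22) and -2.23 (SE 0.11). So did the nucleolar GTPase Gnl2 (-2.21, SE 0.12), the unconventional myosin Myo7a (-2.19, SE 0.19) and the kinase Cdk20 (-2.03, SE 0.21), all with limma adjusted p of 0.00306 or less. Taf12 was above background on 3 Bgn_KO arrays and Myo7a on 2, which makes them at least 7.37-fold and 4.12-fold lower. Ntrk2, the receptor for brain-derived neurotrophic factor, moved both ways. Its probe ILMN_2705460 was above background on all 4 WT arrays and on 0 Bgn_KO arrays, at least 4.68-fold lower (limma adjusted p = 0.00280). ILMN_3061460, named after its values were seen, rose by 1.12 (limma adjusted p = 0.0258) and the brightest probe, ILMN_3138904, had a log2 difference of 0.28 (limma adjusted p = 0.297). Other probes of these genes differed less: that of Cxadr by -0.05, that of Gnl2 by 0.07 and those of Taf12 by -0.16 and -0.43 (limma adjusted p = 0.666 and 0.369). Of those of Cdk20, ILMN_1238557 also fell (-0.47, limma adjusted p = 0.0478), while the others differed by 0.42 and 0.22. Of the 12 probes with the largest falls 4 have no gene name here: ILMN_2769656 (-3.72), ILMN_2666279 (-3.27), ILMN_1214850 (-2.33) and ILMN_3159435 (-2.07), all with limma adjusted p of 0.00234 or less.

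Altogether 72 of the 14190 tested probes passed 0.05, 32 higher and 40 lower in Bgn_KO, from 64 named genes (30 higher and 35 lower, Ntrk2 in both) and 5 probes with no gene name. All 72 had groups whose arrays did not overlap. Over all tested probes 873 did so (6.15%, where chance gives 2.86%), and 1441 had an unadjusted p under 0.05 (709.5 by chance). Of the called probes, 16 were over 2-fold higher and 27 over 2-fold lower. These sizes depend on the background correction: the median absolute log2 difference of the 72 probes was 1.23, and 0.64 without background correction or 0.63 in the authors' processed values. There Erdr1 differed by 2.75 and 2.69, Padi2 by 0.84 and 0.81, Cxadr by -1.34 and -1.30 and Mrps27 by -1.16 and -1.13. The folds given above as bounds hold for the background-corrected signal only. The count fell to 43 without WT replicate 4 and to 44 without WT replicate 3, and it was 52 without the array labelled WT replicate 1. Without Bgn_KO replicate 4 and WT replicate 4 together, left out after seeing that they held cortical and muscle transcripts, it was 43 (15 higher and 28 lower).

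**Figure D2:**
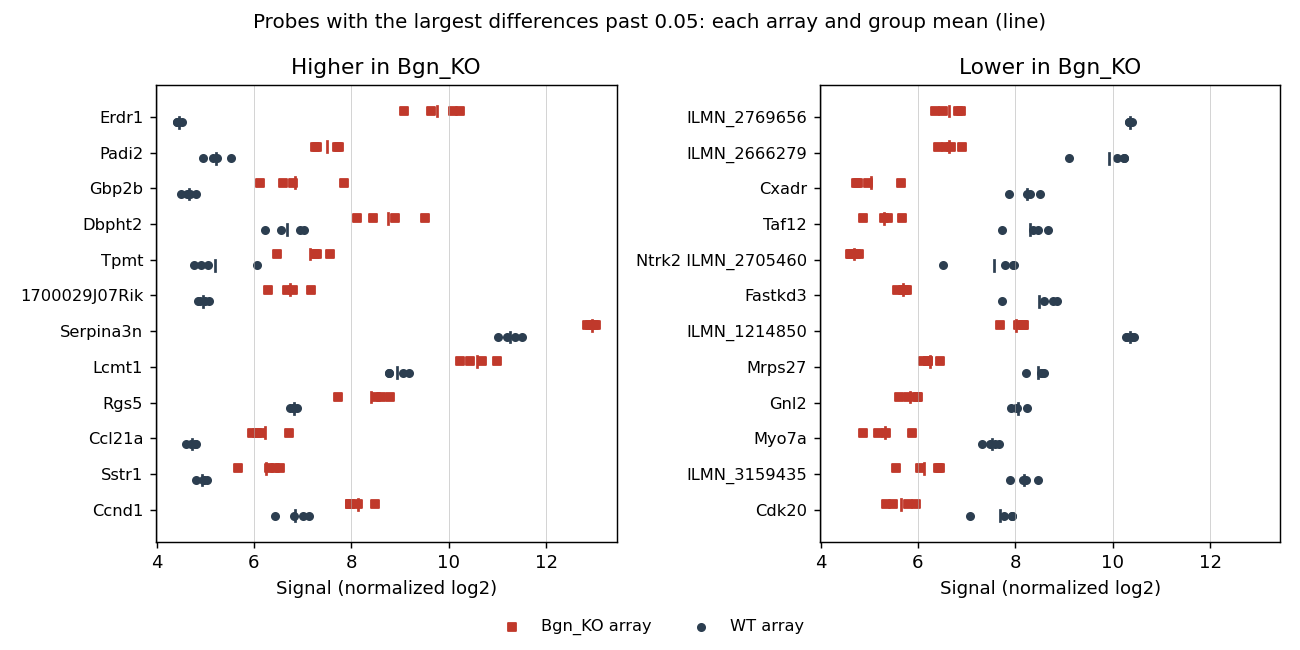
Normalized log2 signal on each array (horizontal axes) for the 12 probes with the largest rise (left) and the 12 with the largest fall (right) among those past 0.05. Squares are Bgn_KO arrays, circles WT arrays (n = 4 each), and lines the group means. The groups do not overlap for any probe drawn, and Erdr1 differs most, 9.76 against 4.46.

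Peptides that control feeding did not pass the test over all probes. The log2 difference was -0.03 (SE 0.21) for Npy, which stimulates feeding, -0.07 (SE 0.32) for Pomc, the precursor of melanocortins that reduce it, -0.12 (SE 0.18) for Cartpt and 0.10 (SE 0.15) for the melanocortin receptor Mc4r, with limma adjusted p between 0.869 and 0.972. No probe on the array was annotated to Agrp, and the 2 probes of the leptin receptor Lepr were above background on 0 arrays. Of 34 measured energy balance genes 17 were higher and 17 lower. Of the stand-in probes, that with the highest mean signal of each gene, 0 passed over all probes and 2, both lower, passed adjusted over the list alone: Hcrt, the precursor of the orexins (-0.45, SE 0.11, limma adjusted p = 0.0346 adjusted over the list alone, limma adjusted p = 0.149 over all probes) and neuropeptide B, Npb (-0.73, SE 0.15, limma adjusted p = 0.0331 and 0.107). The stand-in probe of Ntrk2 and Irs2, an insulin receptor substrate, differed by 0.28 and 0.59 without passing either. For this list the median (-0.01) and the test pointed down and the mean (0.01) up (camera adjusted p = 0.738). Other hypothalamic hormones and peptides were lower for 22 of 27 genes (median log2 difference -0.10, camera adjusted p = 0.0114, adjusted p = 0.762 with an estimated correlation), with 0 members past 0.05 over all probes or adjusted over the list alone. They included Ddc, an enzyme of dopamine and serotonin synthesis (-0.52), the gastrin-releasing peptide Grp (-0.59), the progesterone receptor Pgr (-0.34) and Tacr3, the neurokinin B receptor (-0.25). That list passed neither without Bgn_KO replicate 4 (median -0.01, camera adjusted p = 0.277) nor without the array labelled WT replicate 1 (-0.08, 0.123), and its median was -0.17 without Bgn_KO replicate 1 and -0.16 without WT replicate 2. It was also lost with no filter on dim probes (-0.06, camera adjusted p = 0.0549), with array weights (0.0601) and without both replicates 4 (-0.05, 0.0659). Its median was -0.16 with median scaling, -0.20 with the meningeal list as a covariate and -0.07 without background correction. Thyroid and deiodinase genes (4 of 10 higher, camera adjusted p = 0.506, with the thyroid hormone carrier Ttr at -1.49 and Hr at -0.56) and clock genes (8 of 17 higher, camera adjusted p = 0.766, with Nr1d2 at -0.28 and Csnk1d at 0.23) did not pass, and 0 of their members passed over all probes or adjusted over the list alone.

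Matrix genes, the class to which Bgn belongs, showed no shared shift past the test. Proteoglycans were higher for 10 and lower for 16 of 26 genes (camera adjusted p = 0.533, 0 past 0.05 over all probes or adjusted over the list alone), among them the brain proteoglycans Ncan (0.32) and Cspg5 (0.17) and the cell surface proteoglycan Gpc5 (-0.23). Collagens and fibrillar matrix genes were higher for 12 of 30 (camera adjusted p = 0.383). Col25a1, a transmembrane collagen of neurons, was the only member to pass, adjusted over the list alone (log2 difference 0.60, SE 0.12, limma adjusted p = 0.0224, limma adjusted p = 0.0964 over all probes), while its other probes differed by 0.07, 0.21 and 0.21. Sparcl1, a matrix protein that astrocytes secrete, differed by -0.56 and the laminin chain Lamc1 by -0.31, neither past a threshold. Of 21 matrix proteases and inhibitors 10 were higher and 11 lower. The membrane protease Mmp16 passed adjusted over the list alone (0.68, SE 0.13, limma adjusted p = 0.0119, limma adjusted p = 0.0861 over all probes), and the aggrecan-cleaving Adamts4 (1.15, SE 0.33, limma adjusted p = 0.247) passed only without Bgn_KO replicate 1 (1.53, limma adjusted p = 0.00452). Fcer1g, among chromosome 1 genes that stood apart on that array, also passed only without it. Whether Adamts4 varied with those genes was not tested. For the protease list the median was -0.02, the mean 0.05 and the test pointed up (camera adjusted p = 0.738). TGF-beta and BMP signalling genes were lower for 21 of 29 (median -0.10, camera adjusted p = 0.0406, adjusted p = 0.738 with an estimated correlation), with 0 stand-in probes past 0.05 over all probes or adjusted over the list alone. Id3, Id4 and Tgif1, transcriptional regulators downstream of these ligands, differed by -0.47, -0.60 and -0.63, and the receptor Bmpr1a by -0.26. A dim second probe of the receptor Tgfbr1, ILMN_2980532, named after its values were seen, fell by 0.73 (limma adjusted p = 0.0441), while its stand-in differed by -0.14. The TGF-beta list did not pass without Bgn_KO replicate 2 (camera adjusted p = 0.257), Bgn_KO replicate 3 (median -0.06, 0.115), the array labelled WT replicate 1 (0.0894) or WT replicate 2 (0.188), nor with the meningeal list as a covariate (median -0.05, 0.339) or among probes detected at 0.01 on all arrays (0.0888). Its median was -0.17 without Bgn_KO replicate 4, -0.07 without WT replicate 3, -0.16 without both replicates 4, -0.19 with median scaling (camera adjusted p = 0.111), -0.05 with no filter on dim probes and -0.06 without background correction or in the authors' processed values.

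Most markers of oligodendrocytes and of microglia were lower in Bgn_KO, but these lists passed only with the preset correlation of 0.01. Their estimated correlations were 0.40 and 0.33, so their genes varied together and do not count as separate evidence. Oligodendrocyte markers were lower for 11 of 12 genes (median log2 difference -0.42, camera adjusted p = 1.19e-06, adjusted p = 0.517 with an estimated correlation). None passed over all probes and 6 passed adjusted over the list alone: the myelin proteins Mal (-0.71, SE 0.15), Cldn11 (-0.45, SE 0.11) and Mobp (-0.47, SE 0.16), the iron carrier Trf (-0.52, SE 0.15) and, named after their values were seen, Cnp (-0.29, SE 0.10) and Ugt8a (-0.44, SE 0.16), which makes the myelin lipid galactosylceramide. The mean of the list over arrays differed with an exact permutation p of 0.0571, and the array labelled WT replicate 1 (-0.09) lay within the range of the Bgn_KO arrays (-0.30 to -0.08). Markers of microglia and macrophages were lower for 15 of 16 genes (median -0.32, camera adjusted p = 5.04e-06, adjusted p = 0.517 with an estimated correlation, exact permutation p of the array means 0.0286, the smallest possible). Its separation of the groups rests on Fcer1g. Without that gene the mean of Bgn_KO replicate 4 (0.19) lay above that of 3 WT arrays, the array labelled WT replicate 1 (-0.01) among them, and the exact permutation p was 0.114 (camera adjusted p = 3.96e-05, adjusted p = 0.556 with an estimated correlation). The median of the full list was -0.20 with the meningeal list as a covariate (camera adjusted p = 0.00148) and -0.18 without background correction or in the authors' processed values. Again none passed over all probes, and 5 passed adjusted over the list alone: Ly86 (-0.84, SE 0.18), the microglial membrane protein Tmem119 (-0.39, SE 0.10), the protease Ctss (-0.58, SE 0.19), Fcer1g (-3.83, SE 0.95) and, named after its values were seen, the signalling adaptor Tyrobp (-0.31, SE 0.10). Fcer1g, an Fc receptor chain, was 9.34 on Bgn_KO replicate 1 and at most 4.78 on the other Bgn_KO arrays. Its limma adjusted p of 0.171 became 7.37e-06 without that array. The gene was then above background on 0 Bgn_KO arrays and at least 20.0-fold lower (log2 difference -5.00 as measured, which the background limits). Oligodendrocyte precursors (2 of 6 higher, camera adjusted p = 0.533), astrocytes (4 of 12 higher, 0.125), endothelium (3 of 9 higher, 0.709) and ependyma and tanycytes (1 of 8 higher, 0.450) did not pass, nor did neurons (7 of 12 higher, 0.450), and 0 of their members passed over all probes or adjusted over the list alone. The pericyte and smooth muscle list (5 of 8 higher, camera adjusted p = 0.385) held Rgs5, its only member past 0.05 over all probes and adjusted over the list alone. This list and that of choroid plexus markers each passed by camera under 1 of 20 alternatives and not in the main test.

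Synaptic genes were higher in Bgn_KO for 22 of 25 (median 0.14, camera adjusted p = 0.00158, adjusted p = 0.517 with an estimated correlation). The glutamate receptor subunit Gria1 passed adjusted over the list alone (0.63, SE 0.15, limma adjusted p = 0.0491, limma adjusted p = 0.149 over all probes), and the release machinery genes Rims1 (0.63) and Cplx2 (0.73) did not. Immediate early genes, which neurons induce on activity, were higher for 16 of 20 (median 0.23, camera adjusted p = 0.00813, adjusted p = 0.738 with an estimated correlation). They included Egr1 (0.82), Egr4 (0.85) and Junb (0.64), with 0 members past 0.05 over all probes or adjusted over the list alone. Both lists had their highest mean on Bgn_KO replicate 4, the array on which the list of cortex and hippocampus markers was 1.37 above its mean over arrays and at most 0.02 above it elsewhere. Neither passed without that array, where the medians were somewhat smaller (synaptic genes 0.11, camera adjusted p = 0.0592, immediate early genes 0.18, 0.127), and immediate early genes did not pass without WT replicate 3 (median 0.11, 0.0899). Without both replicates 4 synaptic genes passed (median 0.10, camera adjusted p = 0.0219) and immediate early genes did not (0.16, 0.110). The median of immediate early genes was 0.10 without background correction or in the authors' processed values and 0.14 with no filter on dim probes. The synaptic median was 0.21 without Bgn_KO replicate 3 and 0.06 with median scaling (camera adjusted p = 8.11e-04), which lowered the median of all tested probes from 0.01 to -0.05.

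Oxidative phosphorylation genes were lower for 55 of 68, by a small amount (median log2 difference -0.04, camera adjusted p = 0.00357, adjusted p = 0.572 with an estimated correlation). Members of the ATP synthase, Atp5e (-0.67) and Atp5a1 (-0.32), and of the respiratory chain, Sdhd (-0.35) and Ndufb9 (-0.28), were the lowest by p, with 0 past 0.05 over all probes or adjusted over the list alone. The median of the list was -0.10 with median scaling (camera adjusted p = 8.11e-04), which moved the median of all tested probes from 0.01 to -0.05. Atp5e passed without Bgn_KO replicate 4 (-0.77, limma adjusted p = 0.0459). Interferon response genes were lower for 17 of 19 (median -0.18, camera adjusted p = 0.00813, adjusted p = 0.738 with an estimated correlation). The class I antigen genes B2m (-0.37) and H2-D1 (-0.42) and the immunoproteasome subunit Psmb9 (-0.39) were among them, and 0 passed over all probes or adjusted over the list alone. The interferon list did not pass without Bgn_KO replicate 4 (camera adjusted p = 0.0564), without WT replicate 2 (median -0.08, 0.162) or with the meningeal list as a covariate (-0.10, 0.0849). Its median ranged from -0.34 without Bgn_KO replicate 1 to -0.06 without Bgn_KO replicate 3, and was -0.12 without Bgn_KO replicate 2, -0.28 without WT replicate 4, -0.12 with no filter on dim probes and -0.10 without background correction or in the authors' processed values. The list of genes that vary between mouse strains passed as higher, with 4 of 7 genes higher and 3 lower (median 0.14, mean 0.95, camera adjusted p = 0.0114, adjusted p = 0.517 with an estimated correlation). It rested on Erdr1, its only member past 0.05 over all probes and adjusted over the list alone: without it the camera adjusted p was 0.408. Its median of 0.14 was 0.26 without Bgn_KO replicate 1, 0.01 without Bgn_KO replicate 4 and 0.09 without the array labelled WT replicate 1. It was 0.02 without both replicates 4 or with no filter on dim probes, 0.04 without background correction or in the authors' processed values. It was 0.09 with an offset of 50, 0.08 with array weights and 0.23 with the meningeal list as a covariate. Single genes passed in lists that did not: Sesn2, a stress-induced regulator of growth signalling, rose by 0.82 (SE 0.13, limma adjusted p = 0.0351, and adjusted p = 0.00422 adjusted over the list alone) among 28 heat shock and ER stress genes. The ribosomal protein gene Rps3a1 fell by 1.44 (SE 0.17, limma adjusted p = 0.00654, and adjusted p = 7.43e-04 adjusted over the list alone) among 52. Dhcr7, the last enzyme of cholesterol synthesis, passed adjusted over the list alone (0.75, SE 0.17, limma adjusted p = 0.0241, limma adjusted p = 0.126 over all probes). The call of Sesn2 was lost without Bgn_KO replicate 1, 3 or 4 or WT replicate 1, 3 or 4 (limma adjusted p 0.0702 to 0.118), without both replicates 4 (0.136), without background correction (0.0593) and in the authors' processed values (0.0668).

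Lists of neighbouring tissues and of blood also passed, with the preset correlation only. The exact permutation p of their array means was 0.371 for meningeal fibroblasts, 0.143 for midbrain and hindbrain and 0.0857 for erythrocytes. Meningeal fibroblast markers were lower in Bgn_KO for 15 of 16 genes (median -0.53, camera adjusted p = 0.0114, adjusted p = 0.801 with an estimated correlation), among them the transporter Slc47a1 (-1.04) and the prostaglandin synthase Ptgds (-0.61). Midbrain and hindbrain markers were lower for 5 of 6 (median -0.78, camera adjusted p = 0.0161, adjusted p = 0.738 with an estimated correlation), among them the nicotinic receptor subunit Chrna6 (-1.15) and the dopamine transporter Slc6a3 (-1.81). Erythrocyte markers were lower for 6 of 6 (median -0.28, camera adjusted p = 0.0114, adjusted p = 0.517 with an estimated correlation), with the globin genes Hbb-bt at -0.61 and Hba-a1 at -0.39. In these lists 0 members passed over all probes or adjusted over the list alone. Within both groups the list means varied widely: the meningeal list ranged from -1.03 to 0.69 on Bgn_KO arrays and from -0.54 to 1.10 on WT arrays. The meningeal list did not pass without Bgn_KO replicate 2 (median -0.32, camera adjusted p = 0.118) or 3 (-0.28, 0.251) or WT replicate 2 (-0.22, 0.407) or 3 (-0.36, 0.121), and its median was -0.93 without Bgn_KO replicate 4 and -0.85 without the array labelled WT replicate 1. Midbrain and hindbrain markers did not pass without Bgn_KO replicate 1 (camera adjusted p = 0.101) or 2 (0.113) or WT replicate 2 (median -0.50, 0.102), nor with no filter on dim probes (-0.13, 0.237) or with the meningeal list as a covariate (-0.49, 0.0587), and erythrocyte markers without Bgn_KO replicate 3 (0.0750) or the array labelled WT replicate 1 (0.0775). Without background correction and in the authors' processed values the medians were smaller, -0.34 and -0.33 for the meningeal list, -0.24 and -0.23 for midbrain and hindbrain and -0.15 and -0.14 for erythrocytes. The meningeal median was -1.07 without both replicates 4, -0.89 with array weights and -0.05 with the list itself as a covariate (camera adjusted p = 0.866). The last value follows by construction, since the covariate is the mean of the same list. The median of midbrain and hindbrain was -0.48 with an offset of 50, and that of erythrocytes -0.17 with no filter on dim probes.

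In all, 12 of the 37 tested lists passed 0.05 by camera with its preset correlation, 9 lower and 3 higher. With an estimated correlation 0 passed, and 2 had an unadjusted p under 0.05. By fry, which asks whether a list's genes move one way on balance, 1 passed, the strain list. For glucose and fructose genes the median (0.01) and the test pointed up and the mean (-0.02) down (camera adjusted p = 0.766). With each array scaled to its median in place of quantile normalization 7 lists passed, and 5 were lost. Their medians, beside a median of all tested probes of -0.05, were: TGF-beta and BMP -0.19 (camera adjusted p = 0.111), interferon -0.26 (0.0720), meningeal -0.56 (0.131), midbrain and hindbrain -0.73 (0.131) and erythrocyte -0.33 (0.0864). Cortex and hippocampus markers (9 of 14 higher, camera adjusted p = 0.383) passed without Bgn_KO replicate 1 (0.0465) or 3 (0.0452), and glucocorticoid responsive genes (6 of 17 higher, 0.473) without Bgn_KO replicate 4 (median -0.26, 0.00948).

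**Figure D3:**
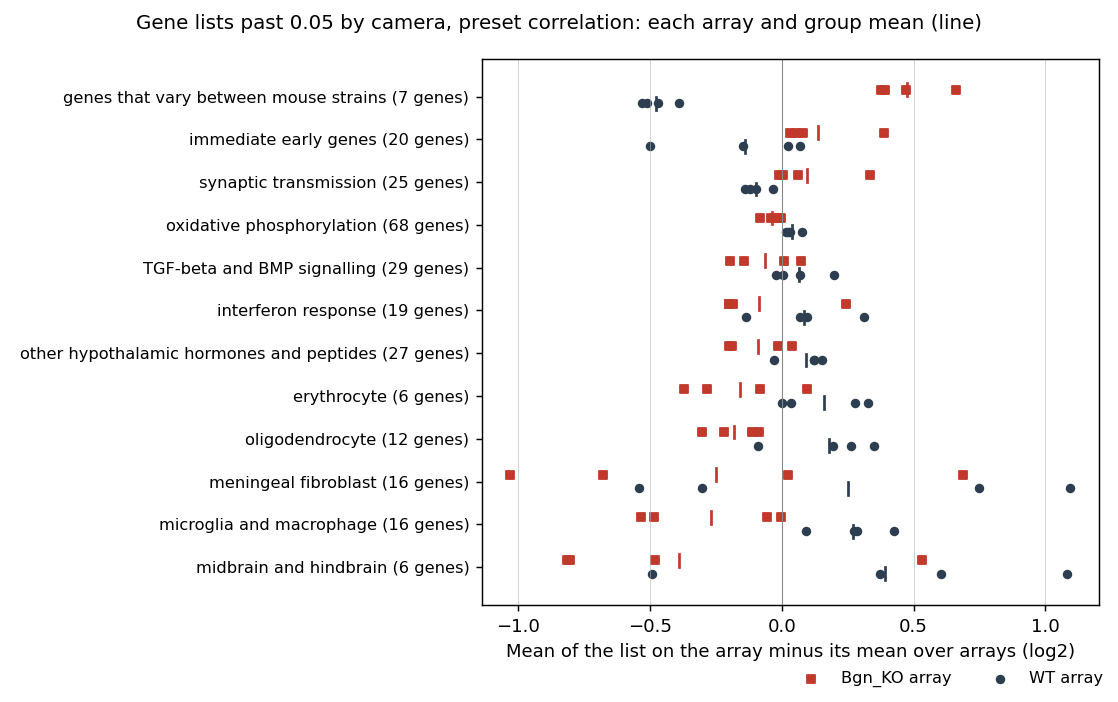
Mean of each gene list on each array minus its mean over arrays, in log2 (horizontal axis), for the 12 lists past 0.05 by camera with its preset correlation. Squares are Bgn_KO arrays, circles WT arrays (n = 4 each), and lines the group means. The Bgn_KO and WT arrays are apart for the strain, oxidative phosphorylation, synaptic and microglia lists. Those of the other lists overlap, for the meningeal list from -1.03 to 0.69 and from -0.54 to 1.10.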

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

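The tests of where the called genes lie, of genes that stand apart on single arrays and of other probes of the called genes were chosen after the calls were seen. Of 258 groups of 4 arrays looked at, 21 held an array far from the other 3, and chance does so in about 1 in 20 groups.

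Among probes named for their change, the array of WT replicate 2 was at 10.41 for ILMN_2769656 (other WT arrays 10.33 to 10.35), at 9.10 for ILMN_2666279 (10.08 to 10.24) and at 6.52 for the Ntrk2 probe ILMN_2705460 (7.78 to 7.98). The array labelled WT replicate 1 was at 8.23 for Mrps27 (other WT arrays 8.53 to 8.58), 6.45 for H2-D1 (5.82 to 5.91), 6.34 for Rims1 (5.74 to 5.82) and 12.34 for Trf (12.75 to 12.82), and its heat shock and ER stress list mean was 0.19 (-0.03 to -0.01). Bgn_KO replicate 4 was at 9.47 for Egr4 (other Bgn_KO arrays 7.91 to 8.12), 6.84 for Chrna6 (5.17 to 5.33), 5.86 for En2 (5.54 to 5.55) and 10.997 for Slc6a3 (7.61 to 7.77). Its list means were 0.39 for immediate early genes (0.03 to 0.08) and 0.55 for pericytes and smooth muscle (-0.12 to -0.06). Bgn_KO replicate 1 was at 5.63 for Kcnj9 (other Bgn_KO arrays 6.65 to 6.75) and 9.34 for Fcer1g (4.55 to 4.78), and its list means were 0.24 for interferon response (-0.20 to -0.19) and 1.24 for pituitary (-0.54 to -0.23). WT replicate 4 was at 8.63 for Atp5e (other WT arrays 8.28 to 8.34), and its list means were -0.0285 for other hypothalamic hormones (0.12 to 0.15) and -0.0593 for X-linked neighbours of Bgn (0.02 to 0.03).

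Genes of chromosome 2, picked after their values were seen, were low together on arrays of both groups. Lrrc57 was at 4.67 and 4.55 on Bgn_KO replicates 1 and 4 and at 4.50 on WT replicate 2, and at 8.43 to 8.77 elsewhere. Cd59a, Rmdn3 and Ccndbp1 were lowest on the same 3 arrays. On chromosome 6 Sspn (4.54, at most 9.74 elsewhere) and Fgfr1op2 (6.89, at most 11.13) were low on WT replicate 4 alone (permutation p = 0.056, adjusted 0.149). On chromosome 8 Zfp330 was at 5.52 on the array labelled WT replicate 1, against 10.10 to 11.29 on the others. There Gipc1 (6.62, mean of the others 8.17) and Usp38 (5.71, 6.99) were also lowest, while Prdx2 (13.64, 13.60) was not. These chromosome 8 genes too were picked after their values were seen.

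Of 600 tested genes on chromosome 4, 21 passed 0.05 (3.5%, adjusted p = 1.78e-09 by a hypergeometric test, exact). Altogether 24 called genes had another called gene within 10 tested genes, while 10000 random placements gave at most 22 (permutation p = 1e-04), so chance placement is argued against. Genes named above were among the 24: Taf12, Sesn2, Padi2, Ccl21a and Ccl21b on chromosome 4, Ntrk2 and Cdk20 on chromosome 13 and 1700029J07Rik on chromosome 8. Their changes may not be independent of those of their neighbours. One explanation is chromosome segments that differ between animals. Genes at which single arrays stood apart from their own group lay near each other on 2 Bgn_KO arrays and on 0 WT arrays. They were Uap1, Fcgr3, Apoa2 and Fcer1g on Bgn_KO replicate 1 (permutation adjusted p = 0.0136) and Rusc2 and Tesk1 on Bgn_KO replicate 2 (0.0256). On Bgn_KO replicate 1 Fcer1g (9.34, WT mean 9.68), Apoa2 (7.66, 7.96), Uap1 (10.16, 10.19) and Fcgr3 (6.83, 7.24) lay near the WT level. On Bgn_KO replicate 2 Rusc2 (11.04, WT mean 11.71) and Tesk1 (9.83, 10.53) lay nearer to WT than to the other Bgn_KO arrays. Such levels go with segments that vary within Bgn_KO, so the differences of these genes need not come from Bgn. The test asked for both groups and left the explanation open. It could not see genes low on 2 arrays of a group, as those of chromosome 2 were on Bgn_KO replicates 1 and 4. On WT replicate 2 Cd59a, Rmdn3 and Lrrc57 stood apart but lay beyond the reach of 10 tested genes. Such genes thus varied within both groups, although they were picked after their values were seen. Skeletal muscle genes were left out of that test after WT replicate 4 had first passed on them. Another explanation, which does not exclude segments, is sequence differences under single probes. Of 33 other probes of called genes, from 22 genes, 8 moved the same way with a limma unadjusted p under 0.05 and 2 the opposite way. Their median log2 difference in the called direction was 0.05, against a median absolute difference of 1.18 for the called probes. The count of 8 of 33 goes with that explanation but does not decide it. Each called probe was the one with the smallest p of its gene, which by itself makes the other probes differ less. At the rate seen over all tested probes 1.68 would move the same way, so some called genes differ at more than 1 probe.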

How the results depend on the processing

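Leaving out Bgn_KO replicate 4 and WT replicate 4 together and the meningeal covariate were chosen after the data were seen, and the others given here before. Against 72 probes past 0.05, there were 47 with 1 probe per gene, 47 among probes detected at 0.01 on all arrays, 116 with array weights, 26 with the replicate number as a block (replicate block, 11 higher and 15 lower), 43 to 76 with 1 array left out and 43 with both replicates 4 left out. There were 119 and 279 at thresholds of 0.1 and 0.2, 1441 and 489 at unadjusted p under 0.05 and 0.01, and 873 without overlap of the groups. Against 12 lists there were 7 with median centring, 0 with an estimated correlation, 1 by fry and 8 to 12 with 1 array left out. The Bgn difference of -0.81 ranged from -1.11 to -0.58 with 1 array left out. For looser or stricter thresholds and fewer arrays the counts move by construction, and elsewhere the cause was not tested. All 72 probes kept their direction wherever they were tested. Of the 20 alternatives 1, the stricter detection filter, left 29 of them untested. With any 1 array left out 37 stayed past 0.05, and 22 did under every alternative that tested them (10 of these were tested under all 20). Replicate numbers are not treated as pairs, since 1 of 4 Bgn_KO arrays correlated best with the WT array of its own number. A slide block was not run because the labels name no slides. Signal near background limits the size of differences, which is why some are given as bounds.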

Other observations

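The sets of muscle, cortex and pituitary genes and the tests of Bgn on the array labelled WT replicate 1 were chosen after the values were seen, and the tests of other splits and of the glial lists were set before their results were seen.

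Some arrays carried transcripts of other tissues. On WT replicate 4 the skeletal muscle genes Acta1 (13.77, at most 9.33 elsewhere), Tnni2 (13.26, at most 5.85), Atp2a1 (14.01, at most 7.28) and Ckm (11.75, at most 4.96) were high. On Bgn_KO replicate 4 the cortical genes Mef2c (10.90, at most 8.38 elsewhere), Itpka (10.69, at most 8.43) and Slc17a7 (11.55, at most 8.88) were high, and the pituitary hormones Prl (7.10) and Gh (7.21) were above background there alone, while the cortical gene Neurod6 was not raised (4.58). The hormone subunits Cga and Tshb were at 8.59 and 8.46 on Bgn_KO replicate 1 and at 9.02 and 7.61 on WT replicate 2.

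Grouping by label was compared with all other splits of the 8 arrays into 4 and 4. The real split gave 72 probes past 0.05 and no other gave over 2, so that 1 of 35 splits had a count as large and chance can be excluded at 5%. The real split gave 12 lists, 4 of 35 splits gave as many and the highest other gave 14, so chance cannot be excluded for the count of lists.

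Bgn on the array labelled WT replicate 1 lay at the level of Bgn_KO (8.86 after quantile normalization, 8.93 with median scaling). A swap with an animal of the Bgn_KO group is argued against by the 52 probes called without that array. Its median position between Bgn_KO (0) and the other WT arrays (1) was 0.997. Left out in the same way, Bgn_KO arrays were at 7.19e-04 to 0.130 and other WT arrays at 0.787 to 1.04. These probes do not read the Bgn allele itself, so the genotype at Bgn is not settled by them. A first bound, which asked for 90% of the probes on the WT side of halfway, was missed with 43 of 52 probes (82.7%, and 82.5% for WT replicate 2), and the comparison with the other arrays was set after that. Little meningeal tissue in the piece could also lower Bgn, and Bgn on that array lay at -0.50 from the line through the other 3 WT arrays against the meningeal list, inside a 95% prediction interval of half-width 1.21. With 1 residual degree of freedom that interval excludes little and this explanation stays open.

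Oligodendrocyte and microglia lists were lower in Bgn_KO by camera with the preset correlation only. Dropping the members found near called genes or apart on single arrays did not end the calls made with the preset correlation. Without Ugt8a, and without Laptm5, Fcer1g and Mrc1, 2 of 2 lists stayed past 0.05 (limma camera adjusted p = 6.01e-06 and 5.40e-05). With an estimated correlation neither list passed, before or after (camera adjusted p = 0.517 for each). Segments shared by 2 arrays of a group could not be found in this way, so members on varying segments are not excluded as a cause. Different amounts of midbrain or hindbrain tissue in the pieces might contribute, since with that list as a covariate 69.1% of the microglial and 82.6% of the oligodendrocyte difference was left. The microglial share rests on Fcer1g: 35.6% was left without it (-0.11, SE 0.10, of -0.32) and 45.9% without all 3 genes, a comparison made after the first share was seen, while 80.9% of the oligodendrocyte difference was left without Ugt8a. With all members neither difference shrank below 50% and neither stayed above it by more than its standard error (-0.37, SE 0.16, for microglia and -0.30, SE 0.13, for oligodendrocytes), so this explanation stays open.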
